A study of Homo sapiens with 10 samples.

How the data were processed

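The series measured polyadenylated RNA by sequencing in HEK293, a human embryonic kidney cell line, in 10 libraries. Per the labels, cells were grown with or without 1 mM 4-thiouridine (4SU), a uridine analogue that is built into new RNA, for 12 to 14 h. They were then crosslinked with ultraviolet light at 365 nm or 254 nm or left without crosslinking. The 4 groups of 2 libraries were 4SU with 365 nm crosslinking, 4SU without crosslinking, 254 nm crosslinking without 4SU, and neither treatment (untreated). The libraries of a group carry the letters A and B. A further pair of libraries, 1 per siRNA, came from cells transfected with an siRNA against HuR or against GFP. Nothing in the labels says that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

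Each deposited file lists transcripts with expected counts of tags, the transcript length, and an expression value that the authors made as tags per 100 nucleotides of transcript per 1000000 tags. The deposited expected counts are not normalized, list only values above 0 and sum to the total of tags in the file header. Fractional counts show that tags matching several transcripts were split between them. The aligner, the genome build and the annotation release are not given in the sources used here. The analysis used the deposited expected counts, rounded to whole tags, and the deposited length. Expression values were not used, and pseudocounts for normalized values were not tried because the files hold counts.

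Transcript accessions were given gene symbols from a reference table of RefSeq accessions, and from GENCODE where that table had none. Of 25005 transcripts, 15886 were named by the first table and 134 by GENCODE alone. The other 8985 stayed unnamed and were tested under their accession: 4154 were GenBank mRNAs, 4504 were RefSeq models and 327 were other RefSeq accessions. The 10 genes with more than 1 transcript were summed, which left 24994 features for 16009 named genes. Features are called genes hereafter. Positions are not reported, since the build is unknown.

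The 8 libraries of the 4 groups were fitted in 1 edgeR 4.0.16 quasi-likelihood model with a mean per group, TMM factors and the filterByExpr filter, under R 4.3.3. It tested 13731 genes with 4 residual and 40 prior degrees of freedom and a common biological coefficient of variation of 0.244. There were 6 contrasts, each with a two-sided test and Benjamini-Hochberg adjustment over all genes, called at an adjusted p under 0.05. Fold changes are on the log2 scale. Their standard error (SE) is an approximation, the size of the fold change divided by the square root of the F statistic of its test. Levels are normalised counts per 1000000 tags (CPM) with the standard deviation (SD) of 2 libraries. Gene lists were fixed before the data were examined. Of 33 lists, 31 had a gene in the files and 26 had the required 5 tested genes. These 26 were tested in 4 contrasts with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. With a correlation estimated from the data, none of the 26 lists passed in any of the 4 contrasts, with or without the length and GC corrections.

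The HuR siRNA pair has no replicate and was not tested. Its log2 ratios used TMM factors and a prior count of 2, with 95% exact counting intervals. Of 17798 genes with at least 10 tags, the 8899 with the higher mean expression were ranked. A list's median was placed as a percentile among 10000 random lists matched on expression. Intervals and the floor of 3 tags cover counting error only. Totals were 2238569 to 3099769 tags in the 8 libraries, where 3 tags equal 0.968 to 1.34 CPM. They were 8688262 and 9016803 tags in the siRNA pair.

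Named genes followed a rule written before the data were examined. For the first 3 contrasts it took the 10 largest increases and 10 largest decreases past the threshold, with all libraries of a group on the same side and mean expression above the median of tested genes. For the siRNA pair it took ELAVL1 and the 10 highest and 10 lowest ratios. It added up to 4 members per list. Changes called largest in the results are the largest under this rule, and genes of lower expression can exceed them. Some genes that the rule takes are not reported here. Values of genes with split tags are uncertain. Beside those marked in the results, these include CDC6, CYBA, DICER1, EEF1D, GCC2, H2AC6, HIF1A, KIF14, MARS2, POLK, POLR2L, RDX, RPL36, RPS27, SELENOH, SESN2, SLC7A5, SP3, TMEM160, UBN2 and XIAP.

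Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile factors, no expression filter, a filter of 5 CPM, the compared groups alone, a replicate block, transcripts as deposited, an adjusted p of 0.01, and leaving out each library. Leaving out a library leaves a group with 1 sample, which is then assumed to vary like the other groups. Library totals without factors for the 8 libraries, and corrections for transcript length and GC content, were added after the data were seen. The length correction removed from each library a lowess trend of the log2 ratio to the mean library on transcript length. Tested on simulated data with the 4SU design, the model recovered 12% of genes changed 2-fold and 77% of genes changed 4-fold. It called 0.0222% of unchanged genes. The simulation drew genes independently and without the differences with transcript length seen between libraries of a group, so these rates may not hold for the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 built tables and plots.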

Results

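The series measured the mRNA of HEK293 cells under the culture and irradiation conditions used to crosslink RNA to RNA-binding proteins before immunoprecipitation (CLIP). The 10 libraries held 4 groups of 2 and 1 library per siRNA. Cells with 4SU and 365 nm crosslinking gave 2402450 tags in library A and 2869446 in library B, and cells with 4SU alone gave 2289523 and 3053932. Cells with 254 nm crosslinking gave 2238569 and 2635373 tags, and untreated cells gave 3099769 and 2396069. The GFP siRNA library had 8688262 tags and the HuR siRNA library 9016803.

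Crosslinked libraries held shorter transcripts than libraries without crosslinking. The tag-weighted median transcript length was 1147 and 1430 nt after 4SU with 365 nm, and 1534 and 1305 nt after 254 nm. It was 2373 and 2849 nt with 4SU alone, and 2666 and 3029 nt in untreated cells. The 10 most abundant transcripts took 12.3% and 8.91% of tags after 4SU with 365 nm, 7.33% and 8.67% after 254 nm, and 2.83% to 3.98% in the 4 libraries without crosslinking. Cytosolic ribosomal protein genes, which encode the protein part of the ribosome, took 32.1% and 22.7% of tags after 4SU with 365 nm and 18.3% and 24.1% after 254 nm. They took 10.1% and 5.91% with 4SU alone and 6.61% and 5.06% in untreated cells.

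**Figure D1:**
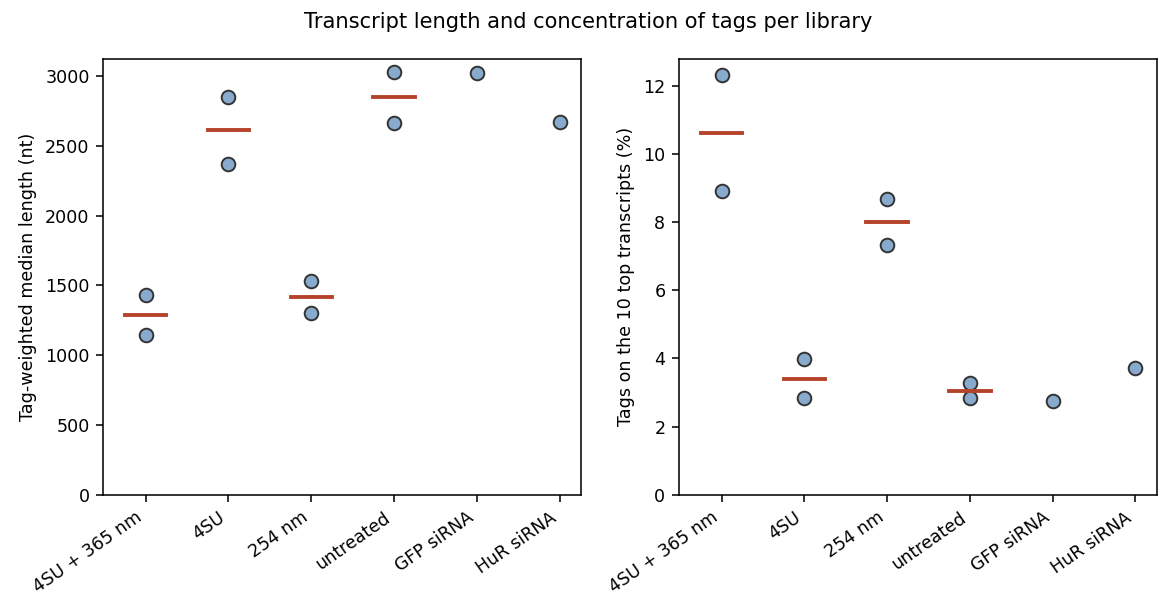
Tag-weighted median transcript length in nucleotides (left) and percent of tags on the 10 most abundant transcripts (right) for each group. Points are libraries and lines are means of the 2 libraries of a group. The 4 crosslinked libraries lie at 1147 to 1534 nt, and the 6 others at 2373 to 3029 nt.

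The first comparison asked what 4SU alone did to mRNA levels. Genes of the integrated stress response, the programme that restores amino acid supply when translation is slowed, were higher as a group, with 10 of 25 past the test (camera adjusted p 1.08e-07, and adjusted p = 0.458 with an estimated correlation). CHAC1, which degrades glutathione, rose from 10.0 ± 5.53 (SD, n = 2) to 55.4 ± 3.17 normalised counts per 1000000 tags (CPM), a log2 fold change of 2.44 with an edgeR adjusted p of 6.98e-05. STC2, a secreted glycoprotein, rose from 47.6 ± 26.7 to 240 ± 45.9 CPM. Genes of cholesterol synthesis were lower, with 7 of 23 past the test (camera adjusted p 7.51e-08, and adjusted p = 0.283 with an estimated correlation). SQLE, which makes squalene epoxide, fell from 342 ± 45.7 to 46.0 ± 20.4 CPM, with a log2 fold change of -2.88 ± 0.38 (SE) and an adjusted p of 2.23e-06. IDI1, an isomerase of the same pathway, fell from 282 to 41.3 CPM, with a log2 fold change of -2.77.

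The 3 largest increases were in WNK4, a kinase that regulates ion transport, KCND1, a potassium channel, and AMH, the anti-Müllerian hormone. WNK4 (NM_032387) rose from 8.51 ± 6.41 to 114 ± 0.51 CPM, with a log2 fold change of 3.78 ± 0.45 and an edgeR adjusted p of 3.61e-07. KCND1 rose by a log2 fold change of 3.75 and AMH by 3.49, from 18.8 ± 8.1 to 213 ± 48.2 CPM. The glycine transporter SLC6A9 (2.86), MROH6 (2.67), the adhesion receptor CELSR3 (2.26) and the stress response gene TRIB3 (2.24) followed. EEF1A1 had 2.30, an uncertain value because some of its tags were split between transcripts. After SQLE and IDI1, the largest decreases included those in the kinase VRK1 (-2.67), NAE1 (-2.53), HMGCS1 (-2.36) and the zinc transporter SLC30A9 (-2.18). SLC12A2, with split tags, had -2.09 and the homeobox gene HOXA13 -2.07.

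By list, 10 of 25 integrated stress response genes rose and none fell, or 11 adjusted over the list alone, with a median log2 fold change of 0.81. Their camera adjusted p was 1.08e-07, and adjusted p = 0.458 with an estimated correlation. Of 23 cholesterol synthesis genes 7 fell and none rose, or 10 adjusted over the list alone, with a median of -0.68, including HMGCS1 and INSIG1 (-1.88). Their camera adjusted p was 7.51e-08, and adjusted p = 0.283 with an estimated correlation. Of 13 replication-dependent histone genes 4 rose, or 10 adjusted over the list alone, with a median of 1.41 (adjusted p 2.14e-06, and adjusted p = 0.458 with an estimated correlation). Their examples were H1-4 (3.19) and H2AC6 (2.39). The histone median was 1.18 with the length correction and 0.83 with length and GC trends removed. The series measured polyadenylated RNA, so these and the later histone values cover polyadenylated histone transcripts only, not all histone mRNA. Of 356 ZNF zinc finger genes, which encode transcription factors, 13 rose and 1 fell, or 11 and 1 adjusted over the list alone, with a median of 0.38 (adjusted p 2.77e-05, and adjusted p = 0.458 with an estimated correlation). ZNF473 had 1.55 and ZNF862 2.34.

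Chaperone and G1/S lists were lower with 4SU. Of 17 heat shock genes 2 fell, HSPA1B (-1.44) and HSPH1 (-1.03), or 4 adjusted over the list alone, with a median of -0.69. Of 18 endoplasmic reticulum chaperone genes 2 fell, MANF (-1.43) and HSPA5 (-1.28, with split tags), also 2 adjusted over the list alone, with a median of -0.53. Both lists had a camera adjusted p of 0.000722, and adjusted p = 0.283 with an estimated correlation. Of 29 G1/S and DNA replication genes 3 fell, among them CCNE1 (-1.62) and CDC6 (-1.38), or 6 fell and 1 rose adjusted over the list alone, with a median of -0.43 (adjusted p 0.00505, and adjusted p = 0.608 with an estimated correlation). The 76 cytosolic ribosomal protein genes had a median of 0.46 with 2 higher, or none adjusted over the list alone (adjusted p 0.00505, and adjusted p = 0.853 with an estimated correlation). Their median was 0.24 with the length correction (adjusted p 0.0424, and adjusted p = 0.888 with an estimated correlation) and 0.22 with length and GC trends removed.

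Proteasome genes (3 of 31 lower, 3 adjusted over the list alone, median -0.20, adjusted p 0.02, and adjusted p = 0.795 with an estimated correlation) were close to the threshold. So were ribosome biogenesis genes (2 of 37 lower, 1 adjusted over the list alone, median -0.27, adjusted p 0.0284, and adjusted p = 0.608 with an estimated correlation). For hnRNP genes, which encode nuclear RNA-binding proteins, 3 of 24 were lower, or 4 adjusted over the list alone, with a median of -0.23 (adjusted p 0.0453, and adjusted p = 0.795 with an estimated correlation). For targets of NRF2, the oxidative stress factor, 3 of 16 were lower, or 4 adjusted over the list alone, with a median of -0.27 (adjusted p 0.0496, and adjusted p = 0.458 with an estimated correlation). The other 14 lists did not pass. Interferon-stimulated genes had 2 of 22 higher and 3 lower, or 3 and 4 adjusted over the list alone, with a camera adjusted p of 0.947. Of 18 pyrimidine metabolism genes CTPS1 (-1.20) fell, of 31 G2 and mitosis genes TOP2A (-1.16) fell, and of 25 p53 target genes 1 rose and 1 fell. No NF-kappaB target, glycolysis, SR protein, miRNA pathway or keratin marker gene passed, of 7, 16, 17, 13 and 5 tested. Known HuR targets had 1 of 35 higher and 5 lower, immediate-early genes 2 of 25 lower, respiratory chain genes 2 of 61 lower, ARE-binding factors 1 of 22 higher and 1 lower, and TOP mRNAs 1 of 20 higher. Adjusted over the list alone, 5 immediate-early genes, 1 respiratory chain gene and 2 ARE-binding factors were lower, and the other counts of these 14 lists were equal.

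The medians of the 12 lists that passed kept their sign with RLE factors, upper-quartile factors and library totals. In total 528 genes rose and 507 fell by the edgeR test with 4SU, of 13731 tested, and 2981 had an unadjusted p under 0.05. With library totals in place of TMM factors, 432 rose and 236 fell. DESeq2 gave 257 and 341, and the replicate block 862 and 831. Of the 66 genes past the threshold that the naming rule takes, 44 lost the call when at least 1 library was left out. Without 4SU library A, 188 rose and 50 fell, and the adjusted p became 0.208 for TRIB3, 0.175 for H1-4, 0.152 for H2AC6, 0.226 for H3C4, 0.475 for H2BC11, 0.137 for MANF, 0.363 for HSPA5, 0.0768 for CCNE1 and HSPA1B, 0.158 for CDC6, 0.391 for HSPH1, 0.25 for CTPS1 and 0.363 for TOP2A. The ribosomal protein list then had the opposite direction, with an adjusted p of 0.385. Without 4SU library B, 302 rose and 200 fell, and the adjusted p became 0.0562 for ZNF862, 0.134 for HSPA1B, 0.122 for HSPH1, 0.0747 for CTPS1, 0.0553 for TOP2A, 0.625 for the proteasome list, 0.281 for the NRF2 list and 0.0625 for the hnRNP list. Without untreated library A, 1290 rose and 1397 fell, and the adjusted p became 0.0671 for HSPA1B and 0.118 for the NRF2 list. Without untreated library B, 332 rose and 249 fell. The adjusted p then became 0.0702 for HSPA5, 0.342 for HSPH1, 0.0922 for CTPS1, 0.249 for TOP2A, 0.144 for the ribosomal protein list, 0.218 for ribosome biogenesis, 0.279 for hnRNP and 0.077 for the proteasome. Leaving out any of the 4 crosslinked libraries moved the hnRNP list to 0.05 to 0.0527 and the NRF2 list to 0.0522 to 0.0557. With the replicate letter as a block the hnRNP and NRF2 lists each had an adjusted p of 0.0523, and with length and GC trends removed the hnRNP list had 0.307 and a median of 0.06. All 4 histone calls were lost without 4SU library A. HSPH1 was at 0.0628, 0.064 and 0.0519 without 4SU with 365 nm library A, library B and 254 nm library B.

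**Figure D2:**
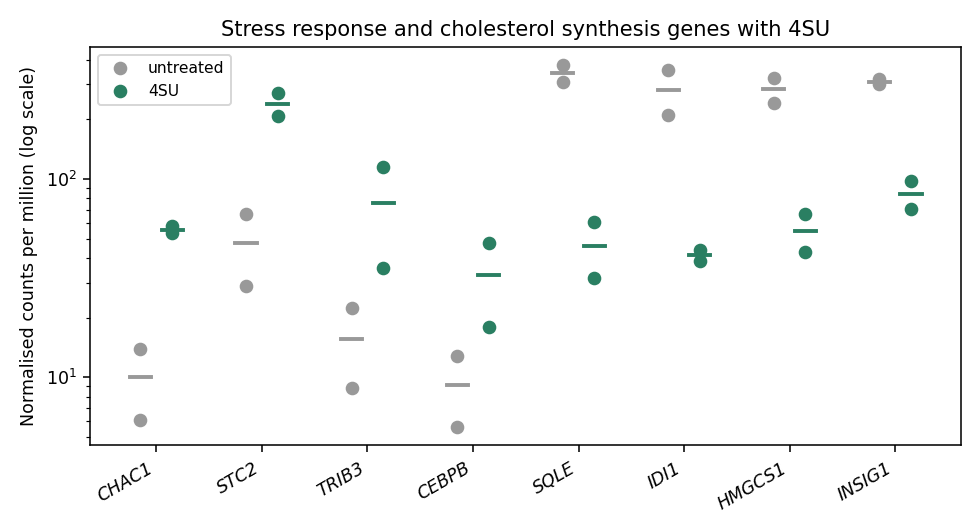
Normalised counts per 1000000 tags (CPM) on a log scale for 4 integrated stress response genes and 4 cholesterol synthesis genes in untreated and 4SU cells without crosslinking. Points are libraries and lines are means of 2 libraries. CHAC1 had a mean of 10.0 untreated and 55.4 with 4SU, and SQLE 342 untreated and 46.0 with 4SU. The calls for TRIB3 and CEBPB were lost without 4SU library A (adjusted p 0.208 and 0.487), and that for CEBPB also without untreated library B (0.0655).

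The next comparison asked which mRNAs differed after 365 nm crosslinking of 4SU cells. All 76 cytosolic ribosomal protein genes rose relative to the other mRNAs, by a median log2 fold change of 3.72, and 60 of 61 nuclear-encoded respiratory chain genes rose, by a median of 3.30. RPS28, a small ribosomal subunit gene, rose from 69.8 ± 40.1 (SD, n = 2) to 1452 ± 79.1 CPM, with a log2 fold change of 4.38 ± 0.48 (SE) and an edgeR adjusted p of 1.51e-09. ZNF zinc finger genes fell, 224 of 356, with a median of -1.79 over the list. With the length correction 126 fell and the median was -1.04. IRS4, an insulin receptor substrate, fell from 182 ± 45.3 to 15.3 ± 1.05 CPM, with a log2 fold change of -3.56 ± 0.42 and an adjusted p of 3.94e-09.

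The further largest increases were in the galectin gene LGALS1 (4.32), RPL3 (4.20), IFI6 (4.20), the phosphatase gene LHPP (4.17), SELENOH (4.16), RPL36 (4.15), IFI27L2 (4.12), the RNA polymerase subunit gene POLR2L (4.12) and RPS27A (4.10). Tags of RPL3, RPL36 and RPS27A were partly split between transcripts, and their values are uncertain. Among genes above the median of expression the largest decrease was in MSMO1, a cholesterol synthesis enzyme, at 3 tags against 144. Its log2 ratio was -3.66 with a 95% exact counting interval of -5.95 to -2.08, and its tags were also partly split. OBI1 (-3.44), the corepressor BCOR (-3.29), RTL6 (-3.27), UBN2 (-3.24), CCDC93 (-3.21), MARS2 (-3.18) and GTPBP2 (-3.15) were also among the largest decreases.

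By list, the ribosomal protein genes (76 adjusted over the list alone) had a camera adjusted p of 2.02e-29, and adjusted p = 0.408 with an estimated correlation. The respiratory chain genes (60 adjusted over the list alone), such as ATP5ME (4.08) and NDUFB8 (4.03), had 4.81e-26, and adjusted p = 0.324 with an estimated correlation. Of 20 translation factor and other TOP mRNA genes, whose translation follows growth signals, 19 rose (19 adjusted over the list alone), with a median of 2.94 and EEF1G at 3.58. Their camera adjusted p was 4.19e-10, and adjusted p = 0.324 with an estimated correlation. Of 31 proteasome genes 23 rose (23 adjusted over the list alone), with a median of 1.99 and PSMB6 at 3.19 (adjusted p 4.69e-08, and adjusted p = 0.418 with an estimated correlation). Of 16 glycolysis genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), with a median of 2.10, including GAPDH (3.61), PFKL (3.59) and LDHB (3.55) (adjusted p 0.00885, and adjusted p = 0.324 with an estimated correlation). Of 18 endoplasmic reticulum chaperone genes 11 rose and 3 fell (11 and 4 adjusted over the list alone), with PDIA3 at 2.91 and CANX at 2.75. Their median was 1.75, and -0.15 with library totals, where the median of all tested genes was -2.40 (adjusted p 0.016, and adjusted p = 0.324 with an estimated correlation). Of 16 NRF2 targets 8 rose and 5 fell (8 and 5 adjusted over the list alone). Their median was 1.32, and -0.60 on that scale (adjusted p 0.0416, and adjusted p = 0.334 with an estimated correlation). All 5 tested keratin markers rose (5 adjusted over the list alone), with EPCAM at 2.73. The SFN call was lost on leaving out any library of either group, at log2 fold changes of 0.96 to 1.44. The keratin median was 1.22, and -0.70 on that scale (camera adjusted p 0.0193, and adjusted p = 0.324 with an estimated correlation).

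Among lists that were lower, the ZNF genes (15 rose and 224 fell, or 16 and 227 adjusted over the list alone) had a camera adjusted p of 8.93e-10, and adjusted p = 0.324 with an estimated correlation. With the 8 ZNF genes that had a group at 0 set to their bound against 3 tags, the median was -1.75. Of 31 G2 and mitosis genes 22 fell and 1 rose (23 and 1 adjusted over the list alone), with a median of -1.36, including the kinesins KIF14 (-2.53) and KIF23 (-2.22) (adjusted p 0.00161, and adjusted p = 0.418 with an estimated correlation). Of 35 known HuR targets 21 fell and 4 rose (21 and 4 adjusted over the list alone), with a median of -1.22, including WNT5A (-2.72) and MYC (-2.52) (adjusted p 0.016, and adjusted p = 0.418 with an estimated correlation). Of 17 SR protein genes, which encode splicing factors, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -1.49, including SRSF4 (-1.97) (adjusted p 0.016, and adjusted p = 0.418 with an estimated correlation). Of 25 immediate-early genes 12 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -1.26, including MCL1 (-2.26) (adjusted p 0.0415, and adjusted p = 0.631 with an estimated correlation).

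The other 13 lists did not pass at 365 nm. Of 24 hnRNP genes 10 rose and 4 fell, with HNRNPA2B1 at 2.90 and a camera adjusted p of 0.068. ARE-binding factors had 12 of 22 lower and 1 higher (0.068), and miRNA pathway genes 6 of 13 lower (0.0887). Genes went both ways among p53 targets (4 of 25 higher, 11 lower), integrated stress response (5 of 25 higher, 12 lower), interferon-stimulated (7 of 22 higher, 4 lower), cholesterol synthesis (6 of 23 higher, 7 lower), heat shock (6 of 17 higher, 3 lower), ribosome biogenesis (8 of 37 higher, 18 lower) and G1/S genes (5 of 29 higher, 11 lower). So they did among histone (2 of 13 higher, 1 lower), NF-kappaB (1 of 7 higher, 3 lower) and pyrimidine metabolism genes (5 of 18 higher, 4 lower). Adjusted over the list alone, 2 ARE-binding factors were higher and 3 pyrimidine genes lower, and the other counts of these 13 lists were equal. The pyrimidine list had a median of -0.17, a mean of 0.31 and an upward camera direction.

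In total 3588 genes rose and 4636 fell by the edgeR test at 365 nm, 3404 and 4417 of them by more than 2-fold. DESeq2 gave 3817 and 2822, the length correction 3599 and 2863, and library totals 1019 and 9965. The median log2 fold change of all tested genes was -0.50, and with RLE factors -0.25, upper-quartile factors -0.64, library totals -2.40 and the length correction -0.21. With the length correction the ribosomal protein median was 1.95, the respiratory chain median 1.68 and the histone median -1.64, and the adjusted p was 0.068 for HuR targets and 0.0506 for keratin markers. ZNF genes had 126 lower and 18 higher with a median of -1.04, and G2 and mitosis genes 13 lower and 1 higher with -0.66. Medians also became 1.09 for proteasome, -0.66 for HuR target, -0.85 for SR protein, -0.69 for immediate-early and 2.07 for keratin genes. The histone list then passed as lower, 9 of 13 genes (adjusted p 0.00363, and adjusted p = 0.278 with an estimated correlation), and the hnRNP list as higher, 14 of 24 genes (adjusted p 0.00162, and adjusted p = 0.414 with an estimated correlation). With length and GC trends removed the SR protein list had an adjusted p of 0.0952, the keratin list 0.186 and the HuR targets 0.05. The medians were then -0.90 for ZNF, -0.54 for G2 and mitosis, 1.36 for glycolysis and 1.09 for chaperone genes. Without 4SU with 365 nm library B, 2847 genes rose and 2376 fell, and the immediate-early list had an adjusted p of 0.312. The immediate-early list had 0.0745 and the keratin list 0.0552 without 4SU library A. The NRF2 list had 0.0642 without 4SU with 365 nm library A, 0.0578 without untreated library A and 0.0583 without untreated library B.

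The 254 nm comparison asked the same of cells without 4SU. All 76 cytosolic ribosomal protein genes rose relative to the other mRNAs, by a median log2 fold change of 2.75, and 53 of 61 respiratory chain genes rose, by a median of 2.48. RPS28 rose from 46.0 ± 29.6 (SD, n = 2) to 681 ± 192 CPM, with a log2 fold change of 3.88 ± 0.47 (SE) and an edgeR adjusted p of 1.63e-07. Regulators of mRNA stability fell, 14 of 22 ARE-binding and related factor genes, with a median of -1.09 over the list. With the length correction 9 fell and the median was -0.68. PHF6, a zinc finger protein of the nucleolus, fell from 61.1 ± 18.6 to 4.21 ± 1.12 CPM, with a log2 fold change of -3.84 ± 0.45 and an adjusted p of 1.34e-07.

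The further largest increases were in NICOL1 (3.88), PCSK1N (3.74), RPS15 (3.71), the NADPH oxidase subunit gene CYBA (3.68), TMEM160 (3.68), RPL36 (3.55), RPS27 (3.53), POLR2L (3.51) and the mitochondrial protein gene CHCHD10 (3.50). The further largest decreases were in the transcription factor genes SP3 (-3.79), ZBTB18 (-3.59) and E2F7 (-3.54), in SBNO1 (-3.78, with split tags), and in the cytokine receptor gene LIFR (-3.60). NEMP1 (-3.59), the membrane linker gene RDX (-3.57), ACSL4 (-3.52) and the tankyrase gene TNKS2 (-3.46) also fell.

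By list, the ribosomal protein genes (76 adjusted over the list alone) had a camera adjusted p of 4.57e-24, the respiratory chain genes (54 adjusted over the list alone) 3.32e-20 and the ARE-binding factors (14 adjusted over the list alone), such as QKI (-3.50), CELF1 (-2.85) and FMR1 (-2.60), 0.000707. Each had adjusted p = 0.524 with an estimated correlation. Of 31 proteasome genes 24 rose (25 adjusted over the list alone), with a median of 1.49 and PSMB6 at 2.63 (adjusted p 2.61e-07, and adjusted p = 0.524 with an estimated correlation). Of 20 TOP mRNA genes 10 rose (10 adjusted over the list alone), with a median of 1.10 and EEF1D at 2.31 (adjusted p 0.00539, and adjusted p = 0.524 with an estimated correlation). Of 35 known HuR targets 18 fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.86, including XIAP (-3.33) and HIF1A (-2.71) (adjusted p 0.00539, and adjusted p = 0.524 with an estimated correlation). Of 356 ZNF genes 141 fell and 41 rose (139 and 41 adjusted over the list alone), with a median of -0.88, with or without 1 gene at its bound (adjusted p 0.00262, and adjusted p = 0.524 with an estimated correlation). Of 13 histone genes 8 rose (8 adjusted over the list alone), including H1-2 (2.89). Their median was 1.27, and -0.55 with the length correction (adjusted p 0.0127, and adjusted p = 0.675 with an estimated correlation).

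SR protein, miRNA pathway and hnRNP lists were also lower at 254 nm. Of 17 SR protein genes 7 fell (7 adjusted over the list alone), with a median of -0.71 and SRRM1 at -2.85 (adjusted p 0.0128, and adjusted p = 0.524 with an estimated correlation). Of 13 miRNA pathway genes 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -1.07 and DICER1 at -2.61 (adjusted p 0.0166, and adjusted p = 0.524 with an estimated correlation). Of 24 hnRNP genes 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.78 (adjusted p 0.0482, and adjusted p = 0.74 with an estimated correlation). The other 15 lists did not pass, and their genes went both ways. G2 and mitosis genes had 5 of 31 higher and 15 lower, with a camera adjusted p of 0.0977, keratin markers 3 of 5 higher and 1 lower (0.176), and pyrimidine metabolism genes 9 of 18 higher and 3 lower (0.172). Counts higher and lower were 4 and 2 of 16 glycolysis genes, 9 and 4 of 25 integrated stress response genes, 7 and 8 of 25 p53 targets, 2 and 6 of 25 immediate-early genes, 4 and 7 of 18 chaperone genes, and 3 and 3 of 17 heat shock genes. They were 10 and 9 of 37 ribosome biogenesis genes, 6 and 6 of 29 G1/S genes, 7 and 9 of 23 cholesterol synthesis genes, 7 and 7 of 22 interferon-stimulated genes, 6 and 7 of 16 NRF2 targets, and 4 and 2 of 7 NF-kappaB targets. Adjusted over the list alone they were 4 and 1 keratin markers, 2 and 2 heat shock genes, 5 and 6 G1/S genes and 7 and 11 cholesterol synthesis genes, and equal for the other lists of these 15.

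In total 3460 genes rose and 3849 fell by the edgeR test at 254 nm, 3138 and 3593 of them by more than 2-fold. Library totals gave 1384 and 6462. The median log2 fold change of all tested genes was -0.14, with upper-quartile factors -0.29 and with library totals -1.0. With the length correction the ribosomal protein median was 1.17 with 51 genes higher, the respiratory chain median was 0.92, and 5 of the 11 list calls were left. Those lost were the proteasome list, at an adjusted p of 0.143, the TOP mRNA list, at 0.099, the ZNF list, at 0.198, the histone list, at 0.383, the miRNA list, at 0.678, and the hnRNP list, at 0.143. ZNF genes then had 61 lower and 49 higher with a median of -0.46, and ARE-binding factors 9 lower and 1 higher with -0.68. Medians also became 0.36 for proteasome, 0.56 for TOP mRNA, -0.46 for HuR target, -0.12 for hnRNP and -0.19 for miRNA pathway genes. With length and GC trends removed the proteasome list passed as higher again, with a median of 0.32 (adjusted p 0.00766, and adjusted p = 0.974 with an estimated correlation). So did the TOP mRNA list, with a median of 0.34 (adjusted p 0.0207, and adjusted p = 0.881 with an estimated correlation). The histone list then passed as lower, with a median of -0.72 (adjusted p 0.0276, and adjusted p = 0.431 with an estimated correlation). The immediate-early list also passed as lower, with a median of -0.78 (adjusted p 0.000645, and adjusted p = 0.72 with an estimated correlation), and the ZNF, hnRNP and miRNA lists had 0.894, 0.658 and 0.939. The ZNF median was then -0.13, the SR protein median -0.47 and the ARE-binding median -0.74. With the replicate letter as a block the hnRNP list had 0.0562. Without 254 nm library B, 2665 genes rose and 2499 fell, and the hnRNP list had an adjusted p of 0.116. The hnRNP list had 0.08 and the histone list 0.0681 without untreated library B, the miRNA list had 0.0555 without 254 nm library A, and the hnRNP list had 0.0658 and 0.0657 without 4SU with 365 nm library A and library B.

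**Figure D3:**
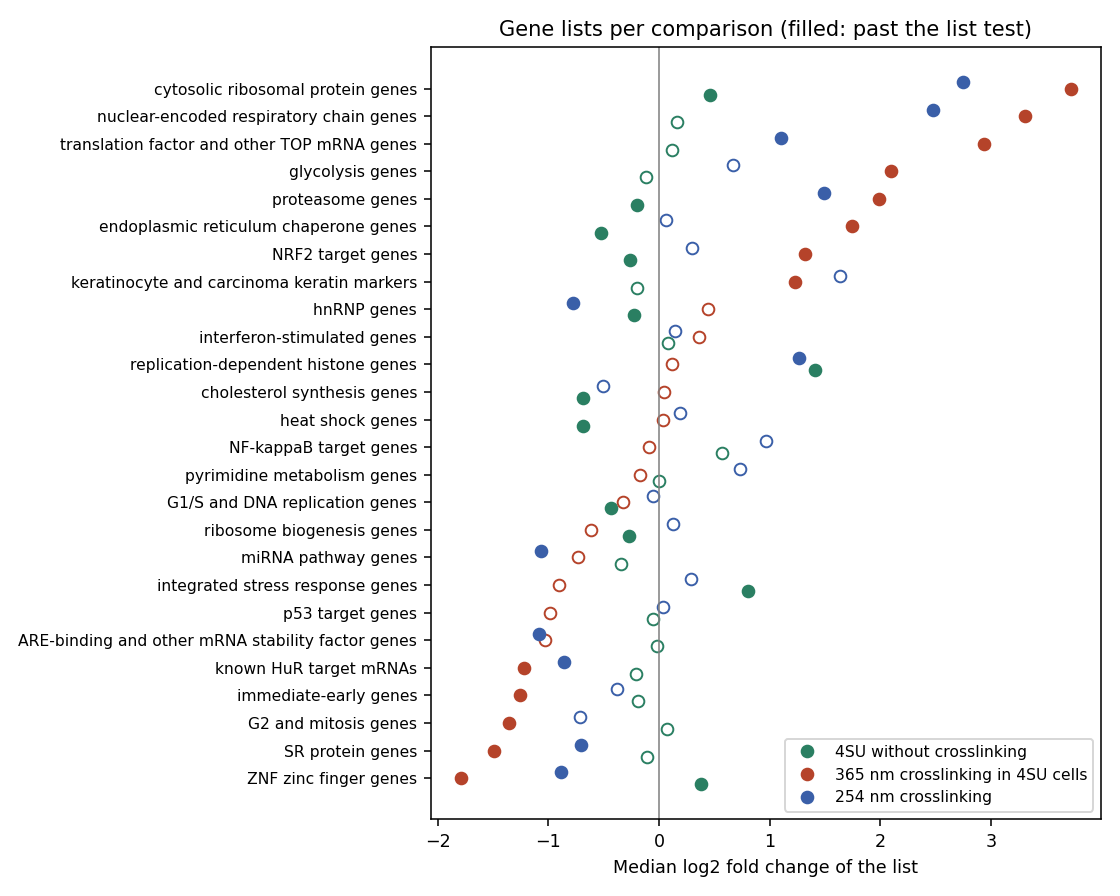
Median log2 fold change of each of the 26 tested gene lists in the 3 comparisons. Filled points passed the camera test at a preset correlation and open points did not. Ribosomal protein genes lie at 3.72 at 365 nm and 2.75 at 254 nm, and ZNF genes at -1.79 and -0.88. With library totals, chaperone, NRF2 and keratin medians at 365 nm are -0.15, -0.60 and -0.70, against -2.40 for all tested genes, and with the length correction the histone median at 254 nm is -0.55.

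Transcript length went with both crosslinking changes. Of the 129 genes with transcripts of up to 500 nt, 70.5% rose at each wavelength, and their median log2 fold change was 2.64 at 365 nm and 2.16 at 254 nm. Of the 630 genes over 8000 nt, 63.7% fell at 365 nm and 75.7% fell at 254 nm, with medians of -1.61 and -1.76. The median tested transcript was 727 nt for ribosomal protein genes, 819 nt for respiratory chain genes, 3303 nt for ZNF genes and 3469 nt for ARE-binding factors. Across genes, which are not independent replicates, Spearman's correlation of the fold change with length was -0.45 at 365 nm, -0.65 at 254 nm and -0.19 for 4SU alone. Without 4SU library A or untreated library B the value for 4SU alone was 0.01 or 0.02.

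**Figure D4:**
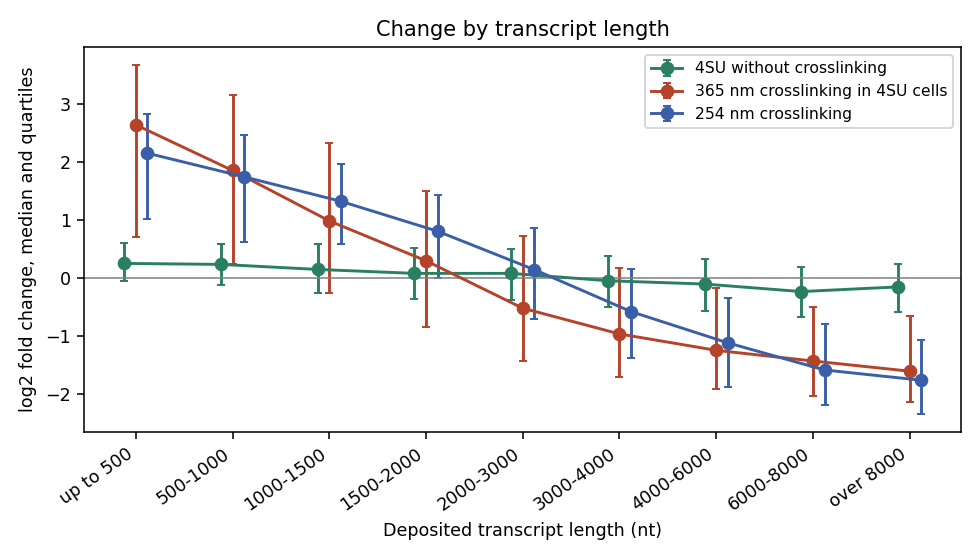
Median log2 fold change against the deposited transcript length in nucleotides, for 4SU alone, 365 nm crosslinking in 4SU cells and 254 nm crosslinking. Points are medians of the genes in a length class and bars are quartiles. Medians go from 2.64 to -1.61 at 365 nm and from 2.16 to -1.76 at 254 nm.

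The responses at both wavelengths were then set against each other, which the 4 groups allow without a shared library. Across the 13731 genes the fold changes had a Pearson correlation of 0.65 and a Spearman correlation of 0.66. By replicate letter r was 0.595 for A and 0.673 for B. Of the genes that rose, 2209 rose at both wavelengths, where 904 would be shared if the calls were independent, and 2550 fell at both, against 1300. A further 347 were called in opposite directions. The 4SU and 254 nm comparisons share the 2 untreated libraries, which cannot be divided into groups of 2 each. Their fold changes had a correlation of 0.288, against 0.439 in simulations with shared controls and no effect, and a covariance of 0.283, against 0.076. No overlap was counted between them.

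Cells crosslinked at 365 nm and their controls had 4SU, and those at 254 nm had none, so wavelength and 4SU cannot be separated in this difference. Testing the difference itself, 1372 genes were higher at 365 nm than at 254 nm relative to their own controls, and 973 were lower. TOP mRNA genes responded more at 365 nm, 9 of 20 higher (12 adjusted over the list alone), with a median difference of 1.77 and EEF1G at 1.93 (adjusted p 1.39e-07, and adjusted p = 0.46 with an estimated correlation). Of 24 hnRNP genes 11 were higher (13 adjusted over the list alone), with a median of 1.30, including HNRNPA2B1 (3.41) and HNRNPM (2.64, with split tags) (adjusted p 1.34e-05, and adjusted p = 0.611 with an estimated correlation). Of 18 chaperone genes 9 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median of 1.26, CANX at 4.65 and PDIA3 at 2.54 (adjusted p 0.000671, and adjusted p = 0.418 with an estimated correlation). Of 16 NRF2 targets 7 were higher (9 adjusted over the list alone), with a median of 1.53 and ME1 at 2.62 (adjusted p 0.00175, and adjusted p = 0.418 with an estimated correlation). Of 16 glycolysis genes 8 were higher (8 and 1 lower adjusted over the list alone), with a median of 1.22 and PFKL at 2.44 (adjusted p 0.0108, and adjusted p = 0.481 with an estimated correlation). Ribosomal protein genes had a median of 0.95 with 1 of 76 higher (none adjusted over the list alone), and -0.11 with library totals, where all tested genes had -1.18. Respiratory chain genes had 0.87 with 6 of 61 higher (6 adjusted over the list alone), and -0.17 on that scale. Both had an adjusted p of 5.56e-06, and adjusted p = 0.62 with an estimated correlation. ZNF genes were lower, 51 of 356 (47 adjusted over the list alone), with a median of -0.86 (adjusted p 1.34e-05, and adjusted p = 0.495 with an estimated correlation). Integrated stress response genes had 7 of 25 lower and 1 higher (7 and 1 adjusted over the list alone) and a median of -0.77, including CHAC1 (-2.39) and STC2 (-2.42). CHAC1 and STC2 were among the largest increases with 4SU alone, a comparison that the difference holds with its sign reversed. Their values here may restate that rise rather than a response to crosslinking. G2 and mitosis genes had 3 of 31 lower (2 adjusted over the list alone) and a median of -0.65, and immediate-early genes 3 of 25 lower (2 adjusted over the list alone) and a median of -0.73, including MYC (-1.81). These 3 lists each had an adjusted p of 0.03, and adjusted p = 0.62 with an estimated correlation. The other 15 lists did not pass.

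With RLE factors the difference had 1673 genes higher and 607 lower, with DESeq2 1583 and 444, and with library totals 494 and 4459. The median difference of all genes was -0.15, with RLE factors 0.06 and with library totals -1.18. Leaving out 4SU with 365 nm library A gave 1054 higher and 389 lower, and library B gave 858 and 246. Leaving out 4SU library A gave 1074 and 404, 254 nm library A 1063 and 458, 254 nm library B 1028 and 636, and untreated library A 1657 and 1859. The stress response list had an adjusted p of 0.164 without 4SU with 365 nm library B, 0.109 without 4SU library A, 0.115 without 254 nm library A and 0.114 without untreated library B. In the same order the immediate-early list had 0.359, 0.0725, 0.105 and 0.0846. With the length correction these lists had 0.0849 and 0.109, and with length and GC trends removed 0.184 and 0.236. The G2 and mitosis median was -0.36 with the length correction, and with length and GC trends removed the glycolysis median was 0.72 and the immediate-early median -0.33. The histone list passed as lower with both (adjusted p 0.00627 and 0.0215), but adjusted p = 0.288 and adjusted p = 0.208 with an estimated correlation. The proteasome list passed as higher with the length correction (adjusted p 0.0163, and adjusted p = 0.673 with an estimated correlation). The G2 and mitosis list had 0.147 without 4SU with 365 nm library B and 0.417 without untreated library A, and the glycolysis list 0.0596 without untreated library A.

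The full 4SU and 365 nm treatment was also compared with untreated cells and with 254 nm crosslinked cells. Against untreated cells 3609 genes rose and 4475 fell, while DESeq2 gave 3835 and 3036, the length correction 3530 and 2887, and library totals 1047 and 9673. The median of all genes was -0.40, with RLE factors -0.17 and with library totals -2.25, and 2730 genes fell without 4SU with 365 nm library B. Against 254 nm crosslinked cells 2092 genes were higher and 1712 lower, while RLE factors gave 2499 and 1219, DESeq2 2316 and 954, and library totals 631 and 5885. The median was -0.10, with RLE factors 0.08 and with library totals -1.08. Leaving out 4SU with 365 nm library A gave 1348 and 773, library B 1377 and 627, and 254 nm library A 1268 and 967. RPL3 and IFI6 had log2 fold changes of 4.09 and 4.04 against untreated cells and 2.19 and 2.14 against 254 nm crosslinked cells. GTPBP2 had -2.90 and -2.18.

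The HuR siRNA library was compared with the GFP siRNA library to see which mRNAs went with a lower level of HuR, an RNA-binding protein that stabilizes AU-rich mRNAs and is encoded by ELAVL1. With 1 library each there was no test. ELAVL1 (NM_001419) had 73.4 CPM against 212, a log2 ratio of -1.53 (95% exact counting interval -1.66 to -1.40). HMOX1, the heme oxygenase gene and an NRF2 target, was higher at 3.27 (3.05 to 3.54), and at 2.10 against the untransfected libraries. Integrated stress response genes were higher, 19 of 22 above 0, with a median of 0.76 at percentile 100 of matched random lists. All 73 ribosomal protein genes were above 0, with a median of 0.67 at percentile 100, and a median of 0.25 against the untransfected libraries.

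The other highest ratios were TP53I13 (1.59), SLC6A9 (1.56), RHBDD2 (1.54), DUS3L (1.51), the amino acid transporter SLC7A5 (1.5), NDUFA2 (1.45), MIIP (1.44), AGPAT2 (1.44, with split tags) and the stress-induced SESN2 (1.42). The lowest were FAM111B (-1.96), SLC4A7 (-1.76), ENPP4 (-1.76), the oligosaccharyltransferase subunit gene STT3B (-1.70), GCC2 (-1.64), CDK17 (-1.62), KIF20B (-1.62), STK26 (-1.59), RIF1 (-1.58) and POLK (-1.57). Of the 8899 ranked genes 237 were over 2-fold higher and 368 over 2-fold lower. Against the mean of the untransfected, untreated libraries TP53I13 was at 0.75, AGPAT2 at 0.85, GCC2 at -0.85, ENPP4 at -1.04, DUS3L at -0.36, SLC7A5 at 0.03, NDUFA2 at 0.02, RHBDD2 at 0.22, SESN2 at 0.21, MIIP at 0.24, CDK17 at -0.30, KIF20B at -0.34 and POLK at -0.47, while STT3B was at -1.82 and RIF1 at -1.55.

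Of 32 known HuR targets 19 were below 0, with a median of -0.17 at percentile 2.7 among lists matched on expression and 8.16 among lists matched also on length, or 17.17 on length and GC content. Respiratory chain genes had a median of 0.51, at percentile 100 and, matched on length, 75.56, or 99.49 on length and GC content. Against the untransfected libraries their median was 0.05, at percentile 79.79. ZNF genes had a median of -0.28, at percentile 0.04 and, matched on length, 7.94. ARE-binding factors had -0.22, at percentiles 3.8 and 16.2. Against the untransfected libraries these lists had -0.10 and -0.03, at percentiles 11.76 and 48.9. NRF2 targets had 0.46, at percentiles 97.87 and 96.96, or 98.85 matched on length and GC content. Their median was 0.07, at percentile 68.77, against the untransfected libraries, and 0.23, at percentile 77.5, with the length correction. The ratio fell with transcript length across genes, with a Spearman correlation of -0.436. Stress response genes stayed at percentile 100 with length matching and against the untransfected libraries, where their median was 0.54. TOP mRNA genes had -0.01, at percentile 6.69 and, matched on length, 1.47, but -0.09 at percentile 27.91 against the untransfected libraries. Among genes of at least 10 CPM on average they had -0.17, at percentile 1.35. The other 14 of the 22 gene lists lay between percentiles 7.54 and 85.03 among lists matched on expression, but not under every alternative. Against the untransfected libraries immediate-early genes went from 0.15 to -0.34, at percentile 2.18, G1/S genes lay at 3.67 and glycolysis genes at 96.59. Cholesterol synthesis and endoplasmic reticulum chaperone genes each lay at 0.02 there. Among genes of at least 10 CPM on average immediate-early genes had 0.31, at percentile 96.48. Matched on length and GC content p53 targets lay at percentile 1.67, G1/S genes at 3.75, G2 and mitosis genes at 97.48 and hnRNP genes at 97.83. With the length correction G1/S genes lay at 1.82 and G2 and mitosis genes at 4.62.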

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

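Tests of varying length loss, of transcript length for the stress response and cholesterol lists, and of a deviating library were chosen after the results were seen. The other tests in this part were chosen before their results were seen.

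The response to crosslinking differed between 365 nm and 254 nm by the edgeR or camera test of the difference. The 365 nm libraries and their controls had 4SU and the 254 nm libraries and theirs had none, so wavelength and 4SU cannot be separated here. RDX had a difference of 3.62: its fold change was 0.06 at 365 nm and -3.57 at 254 nm. Further genes with a larger value at 365 nm were LHPP at 2.43, RPL3 at 2.30, IFI6 at 2.30, PHF6 at 1.94 and SBNO1 at 1.74. Genes with a smaller value at 365 nm were RTL6 at -1.94, GTPBP2 at -2.43 and MSMO1 at -2.78. Tags of RDX, RPL3, SBNO1 and MSMO1 were partly split between transcripts. Lists with a larger median at 365 nm were TOP mRNA genes (1.77), NRF2 targets (1.53), hnRNP genes (1.30), endoplasmic reticulum chaperone genes (1.26), glycolysis genes (1.22), cytosolic ribosomal protein genes (0.95) and respiratory chain genes (0.87). With library totals the ribosomal protein and respiratory chain medians were -0.11 and -0.17, against -1.18 for all tested genes. Lists with a smaller median were ZNF genes (-0.86), integrated stress response genes (-0.77), immediate-early genes (-0.73) and G2 and mitosis genes (-0.65). The difference holds the 4SU comparison with its sign reversed, so the stress response value may restate the rise with 4SU alone. None of the 11 lists passed with an estimated correlation.

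Short mRNAs were higher and long mRNAs lower after both crosslinking steps, with correlations of -0.45 at 365 nm and -0.65 at 254 nm between fold change and length. Without 212 genes, the 200 most abundant and the ribosomal protein genes, the correlation across the 13519 genes left was -0.434 at 365 nm and -0.643 at 254 nm. Tags taken by abundant transcripts move all other genes of a library alike, which gives no trend with length among them. These values thus argue against a few abundant transcripts taking most tags as the cause of the trend among the genes left. A rank correlation does not register a shift common to all genes. Whether abundant transcripts moved the level at which genes count as higher or lower was therefore not decided. A loss of long RNA that varies between preparations whatever the crosslinking is argued against as the whole cause, if preparations differed no more between groups than within them. The tag-weighted median length was 1147 to 1534 nt in the 4 crosslinked libraries and 2373 to 3029 nt in the 6 others, a gap of 839 nt, against at most 476 nt between libraries A and B of a group. The 4SU libraries A and B, which were not crosslinked, differed with length at a correlation of -0.499, and the untreated libraries A and B at -0.403. A part of the pattern thus stays open to such a loss. Preparations that differed between groups are not covered by the comparison of A with B. A loss tied to the irradiation, and a change of mRNA levels in the cells, stay open and untested, because irradiation and RNA preparation were not varied separately.

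Integrated stress response genes were higher and cholesterol synthesis genes lower after 4SU, with medians of 0.81 and -0.68. With the length trend removed the medians were 0.765 and -0.644, and with length and GC trends removed 0.906 and -0.694, which argues against those trends as the whole cause. Across the 4 pairings of a 4SU with an untreated library the stress response median was at least 0.469 and the cholesterol median at most -0.681, which argues against a single deviating library. A hypothesis found and tested on the same libraries is that 4SU culture goes with a stress response and lower expression of cholesterol synthesis genes. In crosslinked cells, 4SU against no 4SU equals the 4SU comparison plus the difference of the crosslinking responses. That difference was -2.39 for CHAC1 and -2.42 for STC2, against rises of 2.44 and 2.32, so little of their rise was left there. SQLE and IDI1 had -0.35 and 0.02, so their decrease stayed. The stress response and cholesterol medians of the difference were -0.77 and 0.17. Wavelength also differed in those cells, so the hypothesis is not decided there. Culture differences that go with the groups, and the estimated-correlation p-values of 0.458 and 0.283, leave the hypothesis open. The HuR siRNA library, whose label names no 4SU, was also compared with the untreated libraries. Its stress response median was 0.54 and its cholesterol median -0.55, against 0.76 and 0.18 relative to the GFP siRNA library. Both directions thus occurred in this library without 4SU when the untreated libraries were the control. It also differed from them in siRNA transfection and in depth. The cholesterol decrease was absent against the GFP siRNA library. Comparison with the untreated libraries alone therefore cannot assign the cholesterol pattern to 4SU. The stress response list was higher against both controls, so its rise may belong to the HuR siRNA library. Whether the untreated libraries alone can give the stress response pattern is thus left open.

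Ribosomal protein mRNAs were higher in the HuR siRNA library than in the GFP siRNA library, with a median log2 ratio of 0.67, and of 0.25 against the untransfected libraries. A length difference between the libraries is argued against as the whole cause, since the median lay at percentile 99.89 of lists matched on length. Their share of tags was 7.22% in the HuR library, 4.99% in the GFP library and 5.06% and 6.61% in untreated libraries. A difference between single transfections and an effect of HuR stay open, as no replicate separates them.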

How the results depend on the processing

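Library totals for the 8 libraries, the length correction and the GC correction were chosen after the data were seen, and the other alternatives were fixed beforehand. Of the values of named genes under alternatives, 5456 kept direction and side of the threshold, 306 were no longer past it, 4 were newly past it and 4 reversed. The reversed values were KRT19 at -0.71, SFN at -0.70 and RRM1 at -0.013 for 365 nm with library totals, and H2BC4 at -0.11 for 254 nm with the length correction. The length correlation of 4SU alone reversed to 0.012 without 4SU library A and 0.018 without untreated library B.

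For 4SU alone, DESeq2 gave 257 genes higher and 341 lower, the replicate block 862 and 831, and an edgeR adjusted p of 0.01 gave 228 and 141. The compared groups alone gave 279 lower and library totals 236. At 365 nm library totals gave 1019 higher and 9965 lower, DESeq2 2822 lower and the length correction 2863 lower. At 254 nm library totals gave 1384 higher and 6462 lower and the length correction 2292 lower. For the difference library totals gave 494 and 4459, an adjusted p of 0.01 gave 875 and 260, DESeq2 444 lower and RLE factors 607 lower. For 4SU with 365 nm against untreated, library totals gave 1047 and 9673 and the length correction 2887 lower. Against 254 nm, library totals gave 631 and 5885, an adjusted p of 0.01 gave 1356 and 862, and DESeq2 954 lower. With an estimated correlation 0 lists were called in each of the 4 contrasts, also after both corrections, and with the length correction 5 at 254 nm. The correlation of the 365 nm and 254 nm responses was 0.537 with the length correction. The 254 nm length correlation was -0.663 with the filter of 5 CPM and -0.686 with the compared groups alone. ELAVL1 was at -1.91 against the untransfected libraries and -1.21 with the length correction, and the HuR target percentile at 0.64 and 2.17. Length and GC corrections together gave 15, 12, 9 and 10 lists called in the 4 contrasts, against 12, 13, 11 and 11, not all the same lists. New with 4SU alone were immediate-early (0.0467), pyrimidine (0.0478) and glycolysis genes (0.0389), lower, and G2 and mitosis genes (0.0103), higher, but adjusted p = 0.715, 0.261, 0.261 and 0.343 with an estimated correlation. Histone genes at 365 nm passed as lower (0.00164) and hnRNP genes as higher (0.00243), but adjusted p = 0.287 and 0.464 with an estimated correlation. Pseudocounts for normalized values were not tried, since the files hold counts. With prior counts of 0.5 and 5 for the siRNA pair ELAVL1 was at -1.53 and -1.52. The causes were not tested.

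Leaving out each library in turn gave 188 to 1290 genes higher and 50 to 1397 lower for 4SU alone, and 2376 to 5069 lower at 365 nm. It gave 2499 to 4219 lower at 254 nm, 858 to 1657 higher and 246 to 1859 lower for the difference, 2730 to 4664 lower for 4SU with 365 nm against untreated, and 1268 to 2390 higher and 627 to 2179 lower against 254 nm. The length correlation was -0.651 to -0.621 at 254 nm, -0.489 to -0.391 at 365 nm and -0.327 to 0.018 for 4SU alone. With the replicate letter as a block, 3703 genes rose and 4904 fell at 365 nm and 3686 and 4085 at 254 nm. With it 10, 13, 10 and 11 lists were called. The A minus B differences correlated at 0.346, 0.149 and 0.127 between the groups of the 3 main comparisons and at 0.05 and 0.008 between those of the other 2 pairs compared, so whether letters mark pairs is open. At this depth, spread and number of libraries 12% of simulated 2-fold changes were recovered.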

Other observations

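The composition tests were chosen before their results were seen, but the narrowing to named genes and the rule for reading the U-rich test were chosen after first values were seen.

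Markers of other cell types were low in all libraries. Erythroid and blood cell markers took 0.00026% to 0.00115% of tags, hepatocyte markers 0% to 0.000306%, fibroblast markers 0.00159% to 0.00512% and keratin markers 0.0354% to 0.0770%. Neuronal lineage markers took 0.217% of tags in the GFP siRNA library and 0.168% in the HuR siRNA library, against 0.0305% to 0.0537% in the untransfected libraries without crosslinking. Of the fibroblast markers 2 and of the neuronal markers 4 were tested. With 4SU alone none passed, at 365 nm 1 fibroblast and 1 neuronal marker rose, and at 254 nm 1 fibroblast marker fell and 1 neuronal marker rose. In the difference both fibroblast markers were higher. Mitochondrially encoded genes and nuclear-retained long noncoding RNAs had no gene in the files, and of the small nucleolar RNA host genes 1 was tested, with a log2 fold change of 0.73 with 4SU, not past the threshold.

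Against the untransfected libraries the HuR siRNA library had a median of -0.55 for cholesterol synthesis genes, at percentile 0.02, and of -0.57 for endoplasmic reticulum chaperone genes, also at percentile 0.02. Against the GFP siRNA library these lists were at 0.18 and 0.14, at percentiles 71.48 and 51.53.

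A hypothesis is that the uridine content of an mRNA, the base in whose place 4SU is built in and at which 254 nm light crosslinks readily, goes with its loss after crosslinking. It was tested on 10720 named genes, 95.7% of those tested by name and 78.1% of all tested, in a family of 28 correlations. The rank correlation of the 254 nm fold change with uridine percent was -0.533. Its permutation p was 1e-05, the smallest that 100000 permutations can give, and the same after adjustment. With transcript length held fixed the rank correlation was -0.556, a value that was not permuted. Genes are not independent replicates, so the p says little beyond the size. Among transcripts of 1500 to 3000 nt the median fold change at 254 nm went from 1.31 in the 764 genes with the least uridine to -0.58 in those with the most. With length held fixed, the correlation at 365 nm was -0.186, between the bounds set for and against the hypothesis. The medians at 365 nm were 0.39 and -0.63.

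With length held fixed, adenine content had correlations of -0.497 at 254 nm and -0.169 at 365 nm. A general GC trend may thus account for the uridine values at 254 nm. At 365 nm each value lay between its bounds, and uridine and GC content cannot be told apart. With 4SU alone and length held fixed, the correlation was -0.357 for uridine and -0.388 for adenine. For the difference of the crosslinking responses it was 0.238 for uridine and 0.209 for adenine. Relative to other mRNAs, uridine-rich mRNAs thus tended to be lowered less at 365 nm in 4SU cells than at 254 nm. The difference holds the 4SU comparison with its sign reversed, so these values may in part restate those of 4SU alone. The length trend stayed with uridine and GC content fixed, at -0.438 for 365 nm and -0.699 for 254 nm.

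A further hypothesis was that mRNAs with many U-rich 3' UTR sites, which HuR binds, were lower in the HuR siRNA library. The 1515 genes with the most sites had a median log2 ratio of -0.40, at percentile 0 of lists matched on expression and length, which met the bound set beforehand for U-rich sites. The median was -0.16 against the untransfected libraries and -0.16 with the length correction, each at percentile 0 of lists matched on expression. Among random lists matched also on GC content, with 5 classes per property and a median of -0.47, they lay at percentile 100. These genes were thus less low than such lists, at -0.40 against -0.47. The random lists could draw the same genes, and genes of a class were not equal in length or GC content. Reading that value against U-rich sites as the cause was decided after it had been seen. The GC value met neither bound set for it, so how GC content acts cannot be told apart from other properties of these genes.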
